A study of Mus musculus with 16 samples.

How the data were processed

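RNA was measured in 16 liver libraries from FVB/NCrl mice, 4 libraries in each of 4 groups given 0, 0.1, 1 or 10 mg/L diphenyl phosphate, named CTRL, C1, C2 and C3 here. The route of administration is not given in the sources used here. Per the labels' protocols, livers were flash frozen after harvest, total RNA was purified on RNeasy columns, and poly(A) RNA from 1 µg was made into libraries with the NEBNext Ultra II Directional kit. Per the series' design text, the livers of a group were pooled before RNA was quantified and the libraries of a group are analytical replicates. The submitters' processing notes name bcl2fastq 2.19.1.403, FastQC 0.11.5, STAR 2.5.2b and GRCm38. The counting program, its strand setting and treatment of reads that match several genes, the annotation release and any filters are not given in the sources used here. Reads from near-identical copies, overlapping genes and antisense partners therefore cannot be assigned with certainty.

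The deposited table holds raw counts of reads per gene, whole numbers that had not been normalised, for 53372 Ensembl gene identifiers in 1 column per library. All 16 columns were used. Symbols and coordinates came from GENCODE M21 on GRCm38, which held 53267 of the identifiers after their version was dropped, 49723 of them with the same symbol; 98 symbols belong to more than 1 identifier. The total count per library was 25650193, 28006101, 33503129 and 24598433 in CTRL, 33387800, 17202318, 14434761 and 21797732 in C1, 45109243, 40652089, 15611309 and 16311207 in C2 and 33189711, 20343210, 19400712 and 18854980 in C3, each from libraries 1 to 4. A gene with 0 counts over the 4 libraries of a group was given a floor of 3 counts over that group, which is 0.0268 CPM in CTRL, 0.0346 in C1, 0.0255 in C2 and 0.0327 in C3, and folds against that floor use pooled counts without TMM scaling. Floors cover counting error only.

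Genes were kept with filterByExpr (17810 of 32916 genes with at least 1 count), scaled by TMM and tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, robust) in R 4.3.3, with 1 model for all 16 libraries and 12 residual degrees of freedom. The model had the group as its term and no replicate block. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05, and a further count took those with an absolute log2 fold change of at least 1. There were 6 comparisons, 3 against CTRL and 3 between treated groups. CPM values are TMM-scaled, and log2 fold changes are from the edgeR fit. The common biological coefficient of variation was 0.189. Pairs of libraries within a group differed by more than counting noise, with chi-square per degree of freedom between 5.90 and 800 over 24 pairs, so that no library was taken for a second copy of another. With 1 pool per group, n = 4 counts libraries, not animals. The principal components used the 5000 most variable genes with a prior count of 2.

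Groups, tests, gene lists, named genes and most of the alternatives were fixed before the data were examined. There were 33 gene lists of liver metabolism, stress, hormone, immune and housekeeping functions and 13 lists of cell type markers, and 3 lists (intestinal genes seen first, intestinal markers not looked at before, nuclear-retained RNA) were added afterwards. Each fixed list was tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01 and again with an estimated one, Benjamini-Hochberg adjusted over lists and the 3 comparisons with CTRL. Members called by edgeR were counted both over all genes and adjusted over the list alone. Named genes followed a rule. For each treated group the 8 genes with the largest rise and the 8 with the largest fall were taken among called genes with a mean of at least 2 CPM in 1 of the groups, no overlap between treated and control libraries and a symbol that is not a predicted model. For each list described, up to 4 called members with the largest change were taken, and the 2 with the highest CPM where fewer than 2 passed. A further 5 per direction were taken among genes called in all 3 groups and 5 per direction between C3 and C1, with Xist, Ddx3y and Alb as checks. Some genes that the rule names are not reported here and are left out of the counts over named genes. The intestinal genes seen first and the nuclear-retained RNAs were chosen after their values were seen.

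The edgeR test was tried on simulated counts of 17810 genes. Of these 17070 passed the filter and 67, 67 and 66 were changed 1.5-, 2- and 4-fold. In C1, C2 and C3 it recovered 22.4%, 31.3% and 19.4% of 1.5-fold changes. It recovered 79.1%, 83.6% and 80.6% of 2-fold and 100% of 4-fold changes, with 10, 8 and 4 false calls among 144, 151 and 137. These rates may not hold for the real libraries, where a wrong division of C2 and C3 gave 6809 calls. Other settings tried were scaling by DESeq2 size factors or upper quartile, no filter or at least 5 CPM in 4 libraries, DESeq2 1.42.0, limma-voom, only the 2 groups compared, the replicate number as a block, glmTreat against a 1.2-fold change, fry, and each library left out in turn. Chosen after seeing the data were the omission of libraries C2-3, C2-4 and C3-4, a nuclear RNA index as a covariate and protein-coding genes only. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.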

Results

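Liver RNA of FVB/NCrl mice was sequenced after exposure to diphenyl phosphate (DPhP), an aryl phosphate ester that is a known metabolite of organophosphate flame retardants. Untreated animals (CTRL) were compared with animals exposed to 0.1 (C1), 1 (C2) or 10 mg/L DPhP (C3). The livers of each group had been pooled before RNA was measured, and the 4 libraries of a group are analytical replicates of 1 pool. The p-values therefore measure technical spread and not the spread between animals. Pool and concentration cannot be separated in this design. The 16 libraries held between 14434761 (C1-3) and 45109243 (C2-1) counts, and 17810 of 53372 genes passed the filter on low counts. Values are mean TMM-scaled CPM (counts scaled to a common library size) ± SD (n = 4), log2 fold changes are given ± SE, and coordinates refer to GRCm38. Alb, the albumin gene and a marker of hepatocytes, stood at 47950 ± 5147 CPM in CTRL. Xist was read in all 16 libraries (915 ± 121 CPM in CTRL), while the Y-linked genes Ddx3y and Eif2s3y had 0 counts in each. Of the sex chromosome list Xist was the 1 member measured, and edgeR called it in 0 of the 3 comparisons with CTRL. It had an unadjusted p under 0.05 in C2 and was called by DESeq2 in 0 comparisons, and adjusted over the list alone it was higher in C2.

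Libraries C2-3, C2-4 and C3-4 stood apart from the others in nuclear-retained RNA. An index put together after the data were seen, the mean log2 CPM of Malat1, Neat1, Xist and Kcnq1ot1, was 10.15, 10.07 and 9.97 in them and at most 9.39 in the other 13. It averaged 8.66 ± 0.246 in CTRL, 9.21 ± 0.154 in C1, 9.53 ± 0.672 in C2 and 9.36 ± 0.410 in C3. Each library of C1 (lowest 9.02) and C3 (lowest 9.10) lay above the highest of CTRL (9.01), while C2 ranged from 8.88 to 10.15. Counts in sense-intronic genes, which lie within introns of other genes, made up 0.0287%, 0.0249% and 0.0219% in C2-3, C2-4 and C3-4 and at most 0.0138% elsewhere. The first principal component held 34.0% of the variance and the next 12.4%, and these libraries lay at the positive end of the first, at 52.7, 64.2 and 30.6. The CTRL libraries lay at its negative end, between -39.3 (CTRL-2) and -13.5 (CTRL-1). Counts at a ribosomal RNA locus made up between 1.05% (C2-2) and 28.4% (C2-4) of a library. Protein-coding genes made up between 59.4% (C2-4) and 87.7%, the latter in CTRL.

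**Figure D1:**
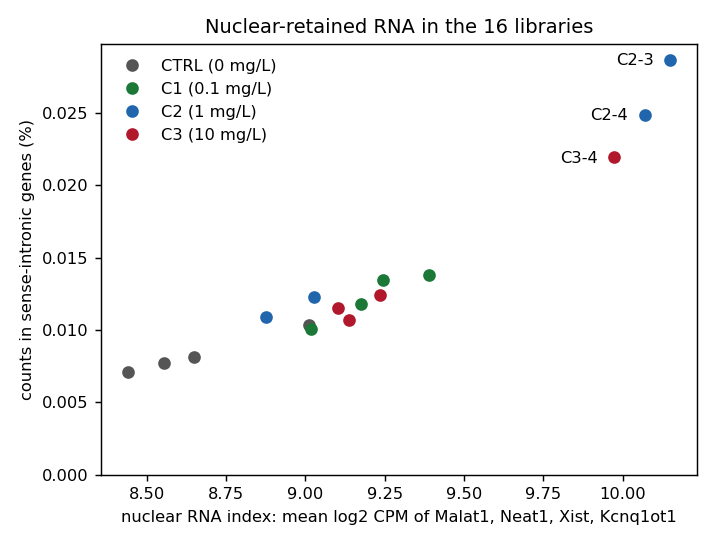
Nuclear-retained RNA in the 16 libraries, with the mean log2 CPM of Malat1, Neat1, Xist and Kcnq1ot1 on the horizontal axis and the percentage of counts in sense-intronic genes on the vertical axis, 1 point per library and 1 colour per group. C2-3 (10.15 and 0.0287%), C2-4 (10.07 and 0.0249%) and C3-4 (9.97 and 0.0219%) lie above the other 13 libraries on both axes.

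The lowest concentration was compared with the untreated pool to ask whether 0.1 mg/L DPhP changed liver transcripts. Of 18 measured glucocorticoid responsive genes 8 fell and 1 rose (edgeR). Of 22 chaperone and unfolded protein response genes 7 fell and 0 rose, and of 31 PPARα targets 6 fell and 2 rose. Zbtb16, a zinc finger transcription factor gene that glucocorticoids induce, rose from 3.99 ± 0.790 CPM in CTRL to 24.3 ± 1.16 in C1 (log2 fold change 2.61 ± 0.21, edgeR adjusted p = 1.88e-06). Igfbp1, which encodes a secreted binding protein for insulin-like growth factors, fell from 222 ± 25.6 CPM in CTRL to 76.4 ± 8.39 in C1 (log2 fold change -1.54 ± 0.18, edgeR adjusted p = 0.000146). In all, 414 genes changed in C1, 167 higher and 247 lower (edgeR, Benjamini-Hochberg adjusted p under 0.05). Of these 106 changed at least 2-fold, 63 higher and 43 lower. Of all 17810 genes tested, 3237 (18.2%) had non-overlapping libraries in C1 and CTRL, which chance alone gives for 2.86%.

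Zbtb16 lies on chromosome 9, 48654297 to 48836222. Ren1, the renin gene, also rose, from 1.43 ± 0.277 CPM in CTRL to 4.70 ± 0.789 in C1 (log2 fold change 1.71 ± 0.28). Lower genes included Adcy1, an adenylate cyclase (log2 fold change -2.30 ± 0.29), and Prok1, a secreted prokineticin (log2 fold change -2.27 ± 0.17). Vnn1, a pantetheinase induced by PPARα, fell from 30.7 ± 4.48 CPM in CTRL to 7.17 ± 0.930 in C1 (log2 fold change -2.09 ± 0.24, edgeR adjusted p = 0.000133). Csad, an enzyme of taurine synthesis (log2 fold change -1.60 ± 0.10), and Ppp1r3g, a glycogen-targeting subunit of protein phosphatase 1 (log2 fold change -1.62 ± 0.32), fell as well. Ddit4, an inhibitor of mTORC1 signalling (log2 fold change -1.74 ± 0.22), and the stress-inducible gene Gadd45g (log2 fold change -1.71 ± 0.30) fell too. Alas1, the rate-limiting enzyme of heme synthesis in liver, fell from 717 ± 43.5 CPM in CTRL to 339 ± 16.5 in C1 (log2 fold change -1.08 ± 0.17).

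Of the PPARα targets, 2 of 31 measured members rose and 6 fell (2 and 8 adjusted over the list alone). For PPARα targets camera gave adjusted p = 6.35e-05, and adjusted p = 0.239 with an estimated correlation. The members with the largest changes were Vnn1 (-2.09), Retsat (-1.28), Cyp4a14 (-1.27) and Cd36 (-1.25), in log2 fold change. Cd36 takes up fatty acids and Cyp4a14 hydroxylates them. Among β-oxidation genes, 0 of 34 measured members rose and 2 fell (0 and 4 adjusted over the list alone). These were Acadm, the medium-chain acyl-CoA dehydrogenase (-0.59), and Crat, carnitine acetyltransferase (-0.43). For β-oxidation genes camera gave adjusted p = 1.41e-06, and adjusted p = 0.462 with an estimated correlation. In the ketone body list 0 of 9 measured members rose and 3 fell (0 and 5 adjusted over the list alone). Bdh1 (-0.76) was among those that fell. For ketone body genes camera gave adjusted p = 0.000452, and adjusted p = 0.197 with an estimated correlation. For fatty acid and triglyceride synthesis 0 of 27 measured members rose and 3 fell (2 and 7 adjusted over the list alone), namely Elovl6 (-0.60), Dgat2 (-0.61) and Pklr (-0.55). For this list camera gave adjusted p = 0.00156, and adjusted p = 0.243 with an estimated correlation. Cholesterol synthesis and SREBP2 targets moved the other way: 3 of 25 measured members rose and 0 fell (7 and 0 adjusted over the list alone). The demethylating oxidase gene Msmo1 rose from 107 ± 9.00 CPM in CTRL to 176 ± 5.18 in C1, with the phosphomevalonate kinase gene Pmvk (0.47) and Insig1 (0.46), a brake on sterol synthesis. For cholesterol synthesis camera gave adjusted p = 3.25e-05, and adjusted p = 0.239 with an estimated correlation. Lipoprotein and lipid droplet genes had 1 higher and 3 lower of 32 (1 and 5 adjusted over the list alone). For lipoprotein genes camera gave adjusted p = 0.00226, and adjusted p = 0.239 with an estimated correlation.

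Among glucocorticoid responsive genes, 1 of 18 measured members rose and 8 fell (3 and 10 adjusted over the list alone). For glucocorticoid responsive genes camera gave adjusted p = 6.10e-07, and adjusted p = 0.172 with an estimated correlation. Zbtb16 was the member that rose. Errfi1, an inhibitor of EGF receptor signalling, fell from 1130 ± 44.6 CPM in CTRL to 497 ± 24.96 in C1, beside Ddit4 and Igfbp1. Of the endoplasmic reticulum chaperone and unfolded protein response genes, 0 of 22 measured members rose and 7 fell (0 and 11 adjusted over the list alone). For chaperone genes camera gave adjusted p = 2.33e-09, and adjusted p = 0.0819 with an estimated correlation. Derl3 (-1.09) and Herpud1 (-0.88) act in degradation of misfolded proteins, and Creld2 (-0.71) and Hyou1 (-0.67) assist folding. In glucose and glycogen metabolism 3 of 26 measured members rose and 4 fell (4 and 9 adjusted over the list alone). For glucose genes camera gave adjusted p = 0.0214, and adjusted p = 0.144 with an estimated correlation. Ppp1r3g and Igfbp1 fell, and the glycogen-targeting subunit gene Ppp1r3c rose (0.86). Immediate early genes went both ways: 4 of 22 measured members rose and 2 fell (5 and 5 adjusted over the list alone). Gadd45g and Myc (-1.21) fell, and Atf3 (1.53) and Nr4a1 (0.96) rose. CAR and PXR response genes had 3 higher and 1 lower of 33 (6 and 1 adjusted over the list alone). For CAR and PXR camera gave adjusted p = 0.0483, and adjusted p = 0.734 with an estimated correlation. Gsta1 (1.00) and Cyp2b13 (0.63) rose and Alas1 fell. Reads of Gsta1 and Cyp2b13 can be shared with near-identical relatives.

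A set of genes characteristic of intestinal epithelium was higher in C1, a list put together after these genes were seen. Of its 10 measured members 6 rose and 0 fell in C1 (8 and 0 adjusted over the list alone). Sis, the sucrase-isomaltase of the brush border, rose from 0.786 ± 0.361 CPM in CTRL to 4.39 ± 1.18 in C1 (log2 fold change 2.47 ± 0.40). Reg1 rose from 1.78 ± 0.511 CPM in CTRL to 7.02 ± 1.07 in C1 (log2 fold change 1.98 ± 0.28). Rbp2, a retinol-binding protein of enterocytes (log2 fold change 1.66 ± 0.34), and Cdh17, an intestinal cadherin (log2 fold change 1.68 ± 0.38), rose as well. Of 5 measured intestinal markers not looked at when the list was made, 1 rose and 0 fell in C1 (4 and 0 adjusted over the list alone). The member that rose was the chemokine gene Ccl25, whose call ended whichever library was left out, and which had 3.75 ± 0.389 CPM in CTRL, 6.26 ± 0.539 in C1, 6.48 ± 2.08 in C2 and 5.44 ± 0.551 in C3, not the order of the intestinal genes. In C2 1 of them rose and 2 fell (1 and 3), and in C3 0 rose and 2 fell (1 and 3). Outside the list, Sult6b2 (log2 fold change 1.78 ± 0.33) and Adh6a (log2 fold change 2.14 ± 0.44) rose in C1.

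Other lists in C1 had these members past the edgeR threshold, given here with the count adjusted over the list alone in brackets. Glycerophospholipid genes had 1 higher and 2 lower of 31 (1 and 2), bile acid genes 0 higher and 1 lower of 26 (1 and 1) and aryl hydrocarbon receptor targets 2 higher and 1 lower of 8 (2 and 1). NRF2 response genes had 2 higher and 1 lower of 21 (3 and 1), amino acid and urea cycle genes 1 higher and 2 lower of 35 (3 and 4) and clock genes 3 higher and 1 lower of 20 (3 and 2). Acute phase genes had 1 higher and 2 lower of 30 (2 and 6), ATF4 response genes 1 higher and 2 lower of 20 (4 and 4) and heat shock genes 0 higher and 1 lower of 16 (0 and 1). Type I interferon genes had 0 higher and 1 lower of 29 (0 and 2), antigen presentation genes 1 higher and 0 lower of 24 (1 and 0) and p53 targets 0 higher and 1 lower of 20 (1 and 2). Female-biased genes had 2 higher and 2 lower of 31 (2 and 5), pericentral genes 2 higher and 0 lower of 26 (2 and 0) and periportal genes 0 higher and 1 lower of 23 (1 and 3). Oxidative phosphorylation genes had 0 higher and 1 lower of 52 (0 and 1), proteasome genes 0 higher and 1 lower of 31 (0 and 1) and hepatocyte markers 0 higher and 1 lower of 10 (0 and 2). Cholangiocyte markers had 1 higher and 0 lower of 9 (1 and 0), B and plasma cell markers 2 higher and 0 lower of 10 (2 and 0) and exocrine pancreas markers 1 higher and 0 lower of 3 (2 and 0). In lists where edgeR called 0 members, the number at an unadjusted p under 0.05 and the number called by DESeq2 were 4 and 2 of 26 for cell cycle genes, 1 and 0 of 23 for male-biased genes, 0 and 0 of 13 for mitochondrial DNA-encoded genes and 2 and 0 of 56 for ribosomal protein genes. They were 1 and 0 of 4 for nuclear-retained RNA, 3 and 1 of 15 for macrophage markers, 6 and 2 of 14 for sinusoidal endothelial markers and 0 and 0 of 15 for stellate cell markers. These numbers were 0 and 0 of 16 for T and NK cell markers, 0 and 0 of 3 for neutrophil markers, 2 and 2 of 5 for erythroid markers and 1 and 1 of 3 for adipocyte markers. Likewise they were 2 and 2 of 6 for mesothelial markers and 3 and 0 of 8 for muscle markers. Adjusted over the list alone, these lists had 0 calls except 1 higher for sinusoidal endothelial markers, 2 lower for erythroid markers, 1 lower for adipocyte markers and 2 lower for mesothelial markers. Without C2-3, C2-4 and C3-4, which are not of C1 or CTRL and enter through the shared model, the numbers higher and lower were 2 and 12 for PPARα targets, 0 and 19 for β-oxidation genes, 0 and 6 for ketone body genes, 3 and 14 for fatty acid synthesis genes and 1 and 10 for lipoprotein genes. Cholesterol synthesis genes had 9 and 0, glucocorticoid responsive genes 3 and 12, chaperone genes 0 and 16, glucose genes 4 and 10 and immediate early genes 6 and 5. CAR and PXR genes had 10 and 3, bile acid genes 3 and 5, amino acid genes 5 and 7, acute phase genes 2 and 11 and ATF4 response genes 4 and 5. Heat shock genes had 0 and 5, male-biased genes 4 and 0, female-biased genes 4 and 11, pericentral genes 6 and 2 and periportal genes 1 and 8. Oxidative phosphorylation genes had 0 and 6, proteasome genes 0 and 8, nuclear-retained RNAs 3 and 0, hepatocyte markers 1 and 5 and sinusoidal endothelial markers 6 and 0. Erythroid markers had 0 and 3, mesothelial markers 0 and 2, muscle markers 0 and 2, glycerophospholipid genes 2 and 5 and aryl hydrocarbon receptor targets 2 and 1. NRF2 response genes had 4 and 2, clock genes 4 and 2, type I interferon genes 2 and 3, antigen presentation genes 3 and 3 and p53 targets 2 and 3. Cell cycle genes had 1 and 1, ribosomal protein genes 0 and 2, macrophage markers 0 and 1, stellate cell markers 1 and 0 and cholangiocyte markers 1 and 0. B and plasma cell markers had 2 and 0, exocrine pancreas markers 1 and 0 and adipocyte markers 0 and 1.

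The C1 count was 204, 207, 245 and 159 without C1-1, C1-2, C1-3 or C1-4, 195, 204 and 187 without CTRL-2, CTRL-3 or CTRL-4, 924 with DESeq2, 2557 with only these 8 libraries in the model, 2688 without C2-3, C2-4 and C3-4 and 3807 with the nuclear RNA index as a covariate, which was higher in each C1 library than in any of CTRL, and the 2-fold count was 69 without C1-4 and 64 without CTRL-4. Of 84 calls for genes named by rule 44 held with each library left out in turn, 14 ended whichever was left out, among them Acadm, Crat, Pklr, Nr4a1, Msmo1, Insig1 and Ccl25, and those of Adh6a, Bdh1, Cdh17, Chka, Cyp2b13, Derl3, Dgat2, Gsta1, Hyou1, Nr1h5 and Rbp2 ended without at least 1 of them.

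The pool given 1 mg/L was compared with CTRL to ask which transcripts differed. Of 30 measured acute phase genes 15 fell and 0 rose, and of 34 β-oxidation genes 14 fell and 0 rose (edgeR). Of 14 sinusoidal endothelial markers 10 rose and 0 fell. Mt2, a metal-binding metallothionein, fell from 47.6 ± 4.88 CPM in CTRL to 10.5 ± 0.721 in C2 (log2 fold change -2.17 ± 0.13, edgeR adjusted p = 3.84e-08). Saa1, a serum amyloid A acute phase gene, fell from 41.4 ± 5.31 CPM in CTRL to 13.8 ± 4.84 in C2 (log2 fold change -1.56 ± 0.21, edgeR adjusted p = 0.000116). Stab2, the hyaluronan receptor of sinusoidal endothelium, rose from 21.7 ± 2.54 CPM in CTRL to 39.4 ± 11.6 in C2 (log2 fold change 0.86 ± 0.19). In C2 3254 genes changed, 1430 higher and 1824 lower (edgeR), of which 876 and 1422 were protein-coding. At least 2-fold changed 903, 540 higher and 363 lower, and 307 with protein-coding genes alone. With upper-quartile scaling the split turned to 1969 higher and 1395 lower, 58.5% higher against 43.9%. Of all 17810 genes tested, 3687 (20.7%) had non-overlapping libraries, against 2.86% by chance.

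In the acute phase list 0 of 30 measured members rose and 15 fell (1 and 16 adjusted over the list alone), and the counts were 7 higher and 14 lower without C2-3, C2-4 and C3-4. Its largest changes were Mt2 (-2.17), Saa2 (-1.71), Saa3 (-1.62) and Saa1 (-1.56), in log2 fold change. For acute phase genes camera gave adjusted p = 1.68e-08, and adjusted p = 0.239 with an estimated correlation. Mt1, the neighbouring metallothionein gene, fell from 152 ± 8.89 CPM in CTRL to 61.2 ± 2.64 in C2. Mt2 lies on chromosome 8, 94172664 to 94173568, and reads from overlapping transcripts cannot be told apart without the strand setting. Saa1 and Saa2 are near-identical copies, so the division of reads between them is uncertain. Of the glucocorticoid responsive genes, 1 of 18 measured members rose and 14 fell (1 and 15 adjusted over the list alone), and the counts were 1 higher and 16 lower without C2-3, C2-4 and C3-4. For glucocorticoid responsive genes camera gave adjusted p = 1.02e-09, and adjusted p = 0.0982 with an estimated correlation. Igfbp1 fell from 222 ± 25.6 CPM in CTRL to 79.4 ± 23.6 in C2, Ddit4 (-1.79) fell too, and Zbtb16 rose (1.11). Antigen presentation and interferon gamma genes had 1 higher and 6 lower of 24 (1 and 9 adjusted over the list alone), and 2 higher and 8 lower without C2-3, C2-4 and C3-4. For antigen presentation camera gave adjusted p = 0.00493, and adjusted p = 0.172 with an estimated correlation. The T cell attracting chemokine genes Cxcl9 (-1.33) and Cxcl10 (-1.14) fell among them.

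Of the β-oxidation genes 0 of 34 measured members rose and 14 fell (0 and 15 adjusted over the list alone), and the counts were 1 higher and 16 lower without C2-3, C2-4 and C3-4. For β-oxidation genes camera gave adjusted p = 1.68e-08, and adjusted p = 0.420 with an estimated correlation. Hadha, the α-subunit of the trifunctional protein, fell from 313 ± 27.7 CPM in CTRL to 165 ± 44.2 in C2, and the short-chain dehydrogenase gene Acads fell too (-0.80). PPARα targets had 1 higher and 12 lower of 31 (1 and 13 adjusted over the list alone), and 3 higher and 15 lower without C2-3, C2-4 and C3-4. For PPARα targets camera gave adjusted p = 0.000120, and adjusted p = 0.239 with an estimated correlation. Vnn1 (-1.62), Cd36 (-1.33) and Retsat (-1.17), a retinol saturase, were among those that fell. In the ketone body list 1 of 9 measured members rose and 3 fell (1 and 3 adjusted over the list alone), and the counts were 2 higher and 3 lower without C2-3, C2-4 and C3-4. Bdh1 (-1.13) was among those that fell. Fatty acid and triglyceride synthesis had 2 higher and 11 lower of 27 (3 and 15 adjusted over the list alone), and 2 higher and 14 lower without C2-3, C2-4 and C3-4. For fatty acid synthesis camera gave adjusted p = 0.000448, and adjusted p = 0.219 with an estimated correlation. Fads2, a desaturase of polyunsaturated fatty acids, fell from 190.1 ± 19.1 CPM in CTRL to 69.6 ± 7.79 in C2 (log2 fold change -1.45 ± 0.14). The acyltransferase gene Gpam (-0.85) and Acly, ATP citrate lyase (-0.68), followed. Lipoprotein and lipid droplet genes had 1 higher and 11 lower of 32 (1 and 12 adjusted over the list alone), and 3 higher and 12 lower without C2-3, C2-4 and C3-4. For lipoprotein genes camera gave adjusted p = 0.000194, and adjusted p = 0.172 with an estimated correlation. Apoa4, an apolipoprotein of triglyceride-rich particles, fell from 786 ± 112 CPM in CTRL to 330 ± 55.2 in C2. In glycerophospholipid synthesis 1 of 31 measured members rose and 8 fell (2 and 10 adjusted over the list alone), and the counts were 4 higher and 10 lower without C2-3, C2-4 and C3-4. For glycerophospholipid genes camera gave adjusted p = 0.00448, and adjusted p = 0.0819 with an estimated correlation. Chka, choline kinase α, was the member that rose (1.13). Bile acid genes had 1 higher and 7 lower of 26 (1 and 7 adjusted over the list alone), including Cyp8b1, which sets cholic acid formation (-1.04), and Acox2 (-0.97), and 6 higher and 9 lower without C2-3, C2-4 and C3-4. For bile acid genes camera gave adjusted p = 0.00687, and adjusted p = 0.486 with an estimated correlation.

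Hepatocyte markers had 0 higher and 4 lower of 10 (0 and 6 adjusted over the list alone), and 2 higher and 3 lower without C2-3, C2-4 and C3-4. For hepatocyte markers camera gave adjusted p = 0.00118, and adjusted p = 0.462 with an estimated correlation. Of the periportal genes 0 of 23 measured members rose and 11 fell (0 and 13 adjusted over the list alone), and the counts were 0 higher and 13 lower without C2-3, C2-4 and C3-4. For periportal genes camera gave adjusted p = 3.75e-07, and adjusted p = 0.0819 with an estimated correlation. Aldh1b1, a mitochondrial aldehyde dehydrogenase, fell from 149 ± 20.6 CPM in CTRL to 54.7 ± 5.84 in C2. Amino acid catabolism and urea cycle genes had 0 higher and 12 lower of 35 (1 and 13 adjusted over the list alone), and 2 higher and 14 lower without C2-3, C2-4 and C3-4. For amino acid genes camera gave adjusted p = 8.33e-06, and adjusted p = 0.239 with an estimated correlation. Got1, an aspartate aminotransferase, had the largest change among them (-0.99). Glucose and glycogen genes had 3 higher and 10 lower of 26 (3 and 12 adjusted over the list alone), and 4 higher and 11 lower without C2-3, C2-4 and C3-4. For glucose genes camera gave adjusted p = 0.00151, and adjusted p = 0.0768 with an estimated correlation. Fbp1, a gluconeogenic phosphatase, fell (-1.12). NRF2 response genes had 1 higher and 8 lower of 21 (1 and 11 adjusted over the list alone), and 2 higher and 7 lower without C2-3, C2-4 and C3-4. Ephx1, an epoxide hydrolase, fell (-0.94). For NRF2 response genes camera gave adjusted p = 0.000355, and adjusted p = 0.414 with an estimated correlation. CAR and PXR genes had 1 higher and 9 lower of 33 (2 and 12 adjusted over the list alone), and 10 higher and 9 lower without C2-3, C2-4 and C3-4. For CAR and PXR camera gave adjusted p = 0.0118, and adjusted p = 0.641 with an estimated correlation. Alas1 (-1.06) and Gsta1 (-0.96) fell.

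Oxidative phosphorylation genes had 0 higher and 11 lower of 52 (0 and 11 adjusted over the list alone), but 23 higher and 12 lower without C2-3, C2-4 and C3-4. There the camera adjusted p was 0.0124 upward, while in all libraries it was 0.00724 downward, and adjusted p = 0.734 with an estimated correlation. Proteasome genes had 0 higher and 7 lower of 31 (0 and 8 adjusted over the list alone), and 14 higher and 5 lower without C2-3, C2-4 and C3-4. For proteasome genes camera gave adjusted p = 0.00423, and adjusted p = 0.734 with an estimated correlation. Ribosomal protein genes had 0 higher and 2 lower of 56 (0 and 0 adjusted over the list alone), and 40 higher and 3 lower without C2-3, C2-4 and C3-4.

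Sinusoidal endothelial markers had 10 higher and 0 lower of 14 (12 and 0 adjusted over the list alone), and 9 higher and 0 lower without C2-3, C2-4 and C3-4. Beside Stab2, Egfl7 (0.77), Oit3 (0.73) and Ptprb (0.71) rose, in log2 fold change, and without those 3 libraries the 4 values were 0.45, 0.39, 0.91 and 0.70. For sinusoidal endothelial markers camera gave adjusted p = 4.03e-08, and adjusted p = 0.0142 with an estimated correlation. Erythroid markers had 0 higher and 3 lower of 5 (0 and 5 adjusted over the list alone), and 0 higher and 3 lower without C2-3, C2-4 and C3-4. For erythroid markers camera gave adjusted p = 0.000194, and adjusted p = 0.239 with an estimated correlation. The α-globin gene Hba-a1 fell from 789 ± 99.1 CPM in CTRL to 362 ± 100.2 in C2. Hba-a2, its near-identical copy (-1.16), and Alas2, of heme synthesis in erythroid cells (-1.13), fell with it. Of the 4 nuclear-retained RNAs, Malat1 (1.05), Neat1 (0.88) and Kcnq1ot1 (1.5) rose, 3 in all (4 adjusted over the list alone), and 1 higher and 0 lower without C2-3, C2-4 and C3-4, where Malat1 (0.28, edgeR adjusted p = 0.113) and Kcnq1ot1 (0.34, adjusted p = 0.165) lost their calls. C2-3 and C2-4 have the highest index.

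In C2 Ube2d2b, which resembles a retrocopy of a ubiquitin-conjugating enzyme gene, rose from 0.428 ± 0.0680 CPM in CTRL to 2.65 ± 0.384 in C2 (log2 fold change 2.62 ± 0.27). The sense-intronic Ppnr rose from 0.702 ± 0.221 CPM in CTRL to 3.33 ± 2.45 in C2 and Fam196a from 0.753 ± 0.405 CPM in CTRL to 3.12 ± 1.97 in C2. Tsix, the antisense partner of Xist (1.69), cannot be separated from Xist reads without the strand setting. Atf3, a stress-induced transcription factor gene, rose from 12.3 ± 1.44 CPM in CTRL to 40.9 ± 10.5 in C2 (log2 fold change 1.73 ± 0.16, edgeR adjusted p = 4.46e-06). Atf3 lies on chromosome 1, 191170296 to 191218039. Nnat (1.54), Flrt1 (1.51) and the linker histone gene Hist1h1d (1.49) followed. Several of these stood highest in C2-3 and C2-4. Without those libraries and C3-4 the log2 fold change was 1.09 for Ppnr, 1.08 for Tsix, 0.93 for Nnat, 1.18 for Hist1h1d, 1.39 for Atf3 and 2.53 for Ube2d2b. Fam196a (0.96, adjusted p = 0.0669) and Flrt1 (0.69, adjusted p = 0.0579) lost their edgeR calls there. Among lower genes, Chac1, which degrades glutathione, fell from 2.72 ± 0.528 CPM in CTRL to 0.499 ± 0.314 in C2 (log2 fold change -2.60 ± 0.33, and -3.42 without those libraries).

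All 10 intestinal genes fell in C2 (0 higher and 10 lower, also adjusted over the list alone, with edgeR; the list was put together after they were seen). Alpi and Akp3, both intestinal alkaline phosphatases with similar sequence, had 239 and 469 counts over the 4 CTRL libraries and 0 over the 4 of C2. Against a floor of 3 counts over the group they were at least 83.9-fold and 165-fold lower. Sis had 87 counts in CTRL and 2 in C2, Reg1 198 and 2, and Rbp2 126 and 3. Muc13, a transmembrane mucin, had 239 and 3, and Prap1 322 and 6. S100g, a vitamin D-dependent calcium-binding protein of the intestine, fell from 2.04 ± 1.04 CPM in CTRL to 0.145 ± 0.104 in C2.

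Remaining lists in C2 had these edgeR calls, with the count adjusted over the list alone in brackets. Cholesterol synthesis genes had 2 higher and 3 lower of 25 (2 and 3), aryl hydrocarbon receptor targets 0 higher and 3 lower of 8 (0 and 4) and clock genes 5 higher and 2 lower of 20 (5 and 2). Immediate early genes had 4 higher and 3 lower of 22 (4 and 4), ATF4 response genes 4 higher and 4 lower of 20 (4 and 6) and heat shock genes 0 higher and 4 lower of 16 (2 and 4). Type I interferon genes had 1 higher and 3 lower of 29 (1 and 3), cell cycle genes 0 higher and 1 lower of 26 (0 and 0) and p53 targets 2 higher and 4 lower of 20 (3 and 5). Male-biased genes had 1 higher and 3 lower of 23 (1 and 5), female-biased genes 1 higher and 4 lower of 31 (1 and 4) and pericentral genes 2 higher and 4 lower of 26 (2 and 4). Macrophage markers had 0 higher and 3 lower of 15 (0 and 3), stellate cell markers 1 higher and 0 lower of 15 (0 and 0) and cholangiocyte markers 1 higher and 0 lower of 9 (1 and 0). B and plasma cell markers had 4 higher and 1 lower of 10 (4 and 1), exocrine pancreas markers 0 higher and 2 lower of 3 (0 and 2) and adipocyte markers 0 higher and 1 lower of 3 (0 and 1). Muscle markers had 0 higher and 2 lower of 8 (0 and 2). Chaperone and unfolded protein response genes had 1 higher and 1 lower of 22 (1 and 1), Derl3 rising (1.32) and Herpud1 falling (-0.78). In lists where edgeR called 0 members, the number at an unadjusted p under 0.05 and the number called by DESeq2 were 1 and 1 of 13 for mitochondrial DNA-encoded genes, 2 and 1 of 16 for T and NK cell markers, 0 and 0 of 3 for neutrophil markers and 1 and 0 of 6 for mesothelial markers. Adjusted over the list alone, these lists had 0 calls. Without C2-3, C2-4 and C3-4, where 18468 genes were tested and some lists had more measured members, the numbers higher and lower were 8 and 3 for cholesterol synthesis genes, 0 and 3 for aryl hydrocarbon receptor targets, 5 and 5 for clock genes, 4 and 12 for immediate early genes and 6 and 2 for chaperone genes. ATF4 response genes had 3 and 7, heat shock genes 6 and 4, type I interferon genes 1 and 2, cell cycle genes 4 and 2 and p53 targets 2 and 6. Male-biased genes had 5 and 5, female-biased genes 7 and 3, pericentral genes 6 and 5, mitochondrial DNA-encoded genes 10 and 0 and macrophage markers 1 and 3. Stellate cell markers had 5 and 1, cholangiocyte markers 1 and 3, B and plasma cell markers 3 and 0, exocrine pancreas markers 0 and 2 and adipocyte markers 0 and 1. Mesothelial markers had 0 and 1 and muscle markers 0 and 2.

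The C2 count was 2046, 2092 and 1972 without CTRL-2, CTRL-3 or CTRL-4, 1492 with only the 8 libraries of the comparison in the model, fewer than the 2557 of C1 in that setting, and 5177 without C2-3, C2-4 and C3-4. Of 149 calls for genes named by rule 108 held with each library left out in turn, and among the rest Malat1 lost its call without C2-4, CTRL-2, CTRL-3 or CTRL-4, and Nnat without C2-4.

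At the highest concentration, 10 mg/L, 10 of 31 measured PPARα targets fell and 0 rose (edgeR). Of 30 acute phase genes 5 rose and 1 fell, and of 22 immediate early genes 4 rose and 0 fell. Saa1 rose from 41.4 ± 5.31 CPM in CTRL to 137 ± 35.4 in C3 (log2 fold change 1.72 ± 0.21, edgeR adjusted p = 0.000275), the reverse of its fall in C2. Lcn2, the iron-siderophore binding protein lipocalin 2, rose from 12.6 ± 0.821 CPM in CTRL to 30.8 ± 7.30 in C3 (log2 fold change 1.29 ± 0.18, edgeR adjusted p = 0.000741). Vnn1 fell from 30.7 ± 4.48 CPM in CTRL to 6.31 ± 1.80 in C3 (log2 fold change -2.28 ± 0.24, edgeR adjusted p = 0.000136). In C3 249 genes changed, 93 higher and 156 lower (edgeR), 82 of them at least 2-fold, 32 higher and 50 lower. Of all 17810 genes tested, 2277 (12.8%) had non-overlapping libraries, against 2.86% by chance.

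Saa1 lies on chromosome 7, 46740497 to 46742980. Acute phase genes had 5 higher and 1 lower of 30 (9 and 2 adjusted over the list alone), and 11 higher and 4 lower without C2-3, C2-4 and C3-4, with a camera adjusted p of 0.0529. Saa2 (1.23) and the interleukin receptor gene Il1r1 (0.47) rose, and the receptor antagonist gene Il1rn fell (-1.18). Of the immediate early genes, 4 of 22 measured members rose and 0 fell (6 and 0 adjusted over the list alone), and the counts were 7 higher and 3 lower without C2-3, C2-4 and C3-4. For immediate early genes camera gave adjusted p = 8.63e-06, and adjusted p = 0.462 with an estimated correlation. Atf3 rose from 12.3 ± 1.44 CPM in CTRL to 47.0 ± 6.94 in C3 (log2 fold change 1.93 ± 0.16) and Fos from 23.6 ± 2.97 CPM in CTRL to 64.8 ± 10.97 in C3. Fosb (1.31) and Cyr61, a matricellular protein gene (1.24), rose too. Arntl, which encodes the clock factor BMAL1, rose from 1.56 ± 0.164 CPM in CTRL to 4.97 ± 0.838 in C3 (log2 fold change 1.67 ± 0.20). Clock genes as a list had 1 higher and 0 lower of 20 (1 and 0 adjusted over the list alone). Clic3, a chloride channel family gene (log2 fold change 1.72 ± 0.28), and Ptgds, a prostaglandin D synthase (log2 fold change 1.35 ± 0.24), rose, while the keratin gene Krt23 fell (log2 fold change -1.47 ± 0.16).

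PPARα targets had 0 higher and 10 lower of 31 (1 and 14 adjusted over the list alone), and 0 higher and 15 lower without C2-3, C2-4 and C3-4. For PPARα targets camera gave adjusted p = 2.17e-11 (0.0819 with an estimated correlation). Cd36 fell from 44.3 ± 6.36 CPM in CTRL to 17.7 ± 1.83 in C3, and Cyp4a14 (-1.04) and Retsat (-0.97) fell beside Vnn1. Of the β-oxidation genes 0 of 34 measured members rose and 4 fell (0 and 13 adjusted over the list alone), and the counts were 0 higher and 17 lower without C2-3, C2-4 and C3-4. For β-oxidation genes camera gave adjusted p = 5.35e-12 (0.265 with an estimated correlation). Cpt1a, the gate for entry of fatty acids into mitochondria (-0.53), and the carnitine carrier gene Slc25a20 (-0.46) were among them. Ketone body genes had 1 higher and 2 lower of 9 (1 and 4 adjusted over the list alone), and 1 higher and 3 lower without C2-3, C2-4 and C3-4. Fatty acid and triglyceride synthesis had 1 higher and 4 lower of 27 (1 and 11 adjusted over the list alone), and 2 higher and 11 lower without C2-3, C2-4 and C3-4. For fatty acid synthesis camera gave adjusted p = 0.00164, and adjusted p = 0.243 with an estimated correlation. Fads2 (-0.72), Acly (-0.47) and Elovl6 (-0.40) fell. Cholesterol synthesis genes had 2 higher and 0 lower of 25 (2 and 0 adjusted over the list alone), Insig1 (0.61) and Pmvk (0.50), and 10 higher and 0 lower without C2-3, C2-4 and C3-4. For cholesterol synthesis camera gave adjusted p = 0.00291, and adjusted p = 0.435 with an estimated correlation. Female-biased liver genes had 0 higher and 4 lower of 31 (1 and 10 adjusted over the list alone), and 1 higher and 11 lower without C2-3, C2-4 and C3-4. For female-biased genes camera gave adjusted p = 1.76e-06, and adjusted p = 0.486 with an estimated correlation. Cyp17a1, a steroid hydroxylase, fell from 24.2 ± 2.08 CPM in CTRL to 9.43 ± 2.18 in C3, and Cyp2a22 fell (-0.52), with reads possibly shared among Cyp2a copies. NRF2 response genes had 0 higher and 2 lower of 21 (1 and 4 adjusted over the list alone), G6pdx, of the pentose phosphate pathway (-0.73), and Ephx1 (-0.68), and 1 higher and 5 lower without C2-3, C2-4 and C3-4. For NRF2 response genes camera gave adjusted p = 0.000238, and adjusted p = 0.403 with an estimated correlation. Glucose and glycogen genes had 1 higher and 1 lower of 26 (2 and 4 adjusted over the list alone), and 2 higher and 11 lower without C2-3, C2-4 and C3-4. For glucose genes camera gave adjusted p = 0.00275, and adjusted p = 0.0819 with an estimated correlation. Erythroid markers had 0 higher and 2 lower of 5 (0 and 3 adjusted over the list alone), Hba-a1 (-1.12) and Hba-a2 (-1.14), and 0 higher and 3 lower without C2-3, C2-4 and C3-4. For erythroid markers camera gave adjusted p = 2.37e-05, and adjusted p = 0.178 with an estimated correlation.

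The 10 intestinal genes all fell in C3 as well (0 higher and 10 lower, also adjusted over the list alone). Alpi had 239 counts in CTRL and 5 in C3, Akp3 469 and 22, Muc13 239 and 3, and Prap1 322 and 26. S100g fell from 2.04 ± 1.04 CPM in CTRL to 0.245 ± 0.117 in C3 (log2 fold change -3.08 ± 0.49). Remaining lists in C3 had these edgeR calls, with the count adjusted over the list alone in brackets. Glycerophospholipid genes had 1 higher and 0 lower of 31 (1 and 3), lipoprotein genes 0 higher and 1 lower of 32 (0 and 5) and glucocorticoid responsive genes 0 higher and 1 lower of 18 (3 and 4). ATF4 response genes had 2 higher and 0 lower of 20 (4 and 1), heat shock genes 1 higher and 0 lower of 16 (2 and 0) and type I interferon genes 0 higher and 1 lower of 29 (0 and 1). Antigen presentation genes had 1 higher and 0 lower of 24 (2 and 0), cell cycle genes 0 higher and 1 lower of 26 (0 and 3) and pericentral genes 1 higher and 0 lower of 26 (4 and 1). B and plasma cell markers had 0 higher and 1 lower of 10 (0 and 2), exocrine pancreas markers 0 higher and 2 lower of 3 (0 and 2) and mesothelial markers 0 higher and 1 lower of 6 (0 and 1). The pericentral transcription factor gene Tbx3 (0.77) and the choline kinase gene Chka (1.24) rose among them. In lists where edgeR called 0 members, the number at an unadjusted p under 0.05 and the number called by DESeq2 were 8 and 3 of 26 for bile acid genes, 8 and 3 of 33 for CAR and PXR genes, 2 and 0 of 8 for aryl hydrocarbon receptor targets and 5 and 3 of 35 for amino acid genes. They were 3 and 0 of 22 for chaperone genes, 2 and 1 of 20 for p53 targets, 5 and 1 of 23 for male-biased genes and 3 and 1 of 23 for periportal genes. These numbers were 8 and 2 of 52 for oxidative phosphorylation genes, 0 and 0 of 13 for mitochondrial DNA-encoded genes, 2 and 0 of 56 for ribosomal protein genes and 7 and 1 of 31 for proteasome genes. Likewise they were 3 and 1 of 4 for nuclear-retained RNA, 4 and 1 of 10 for hepatocyte markers, 3 and 0 of 15 for macrophage markers and 4 and 0 of 14 for sinusoidal endothelial markers. Finally they were 1 and 0 of 15 for stellate cell markers, 4 and 0 of 9 for cholangiocyte markers, 1 and 0 of 16 for T and NK cell markers and 3 and 2 of 3 for neutrophil markers. Beyond these they were 0 and 0 of 3 for adipocyte markers and 0 and 0 of 8 for muscle markers. Adjusted over the list alone, these lists had 0 calls except 2 higher for bile acid genes, 4 lower for bile acid genes, 1 higher for male-biased genes, 1 lower for periportal genes, 3 higher for nuclear-retained RNA, 1 higher for cholangiocyte markers, 1 lower for cholangiocyte markers and 3 higher for neutrophil markers. Without C2-3, C2-4 and C3-4 the numbers higher and lower in C3 were 3 and 0 for nuclear-retained RNAs, 2 and 7 for glucocorticoid responsive genes, 4 and 7 for CAR and PXR genes, 5 and 5 for bile acid genes and 1 and 7 for lipoprotein genes. Glycerophospholipid genes had 1 and 5, oxidative phosphorylation genes 1 and 6, hepatocyte markers 0 and 4, amino acid genes 3 and 2 and male-biased genes 5 and 1. Periportal genes had 2 and 4, pericentral genes 3 and 3, clock genes 2 and 3, ATF4 response genes 3 and 3 and heat shock genes 2 and 0. Antigen presentation genes had 3 and 1, type I interferon genes 1 and 1, cell cycle genes 0 and 2, p53 targets 1 and 1 and chaperone genes 0 and 3. Aryl hydrocarbon receptor targets had 0 and 1, mitochondrial DNA-encoded genes 1 and 0, ribosomal protein genes 0 and 0, proteasome genes 0 and 3 and macrophage markers 0 and 1. Sinusoidal endothelial markers had 1 and 1, stellate cell markers 0 and 0, cholangiocyte markers 0 and 1, B and plasma cell markers 0 and 1 and T and NK cell markers 0 and 0. Neutrophil markers had 1 and 0, exocrine pancreas markers 0 and 2, adipocyte markers 0 and 1, mesothelial markers 0 and 1 and muscle markers 0 and 1.

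The C3 count was 145, 123 and 107 without C3-1, C3-3 or C3-4, 152, 105, 97 and 123 without CTRL-1, CTRL-2, CTRL-3 or CTRL-4, 768 with DESeq2, 1125 without C2-3, C2-4 and C3-4 and 3027 with the nuclear RNA index as a covariate, which was higher in each C3 library than in any of CTRL, and the 2-fold count was 54, 48, 50 and 46 without C3-3, C3-4, CTRL-2 or CTRL-3. Of 62 calls for genes named by rule 34 held with each library left out in turn, 3 ended whichever was left out, Acly among them, and those of Cpt1a, Cyp2a22, Cyp4a14, Ephx1, Fads2, Fosb, G6pdx, Il1rn, Nr1h5, Slc25a20 and Tbx3 ended without at least 1 of them. Outside the rule, Elovl6 ended whichever was left out (adjusted p up to 0.141) and Il1r1 without C3-4, CTRL-3 or CTRL-4 (up to 0.0730).

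**Figure D2:**
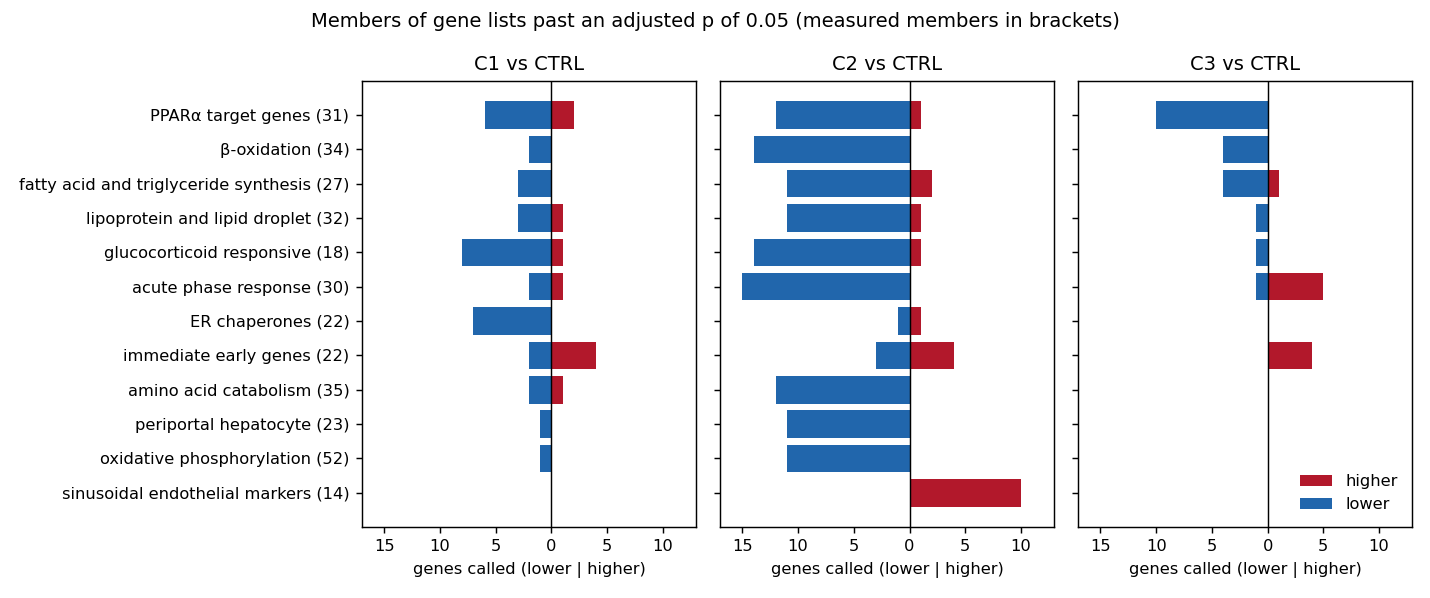
Members of gene lists called higher (red, to the right) or lower (blue, to the left) than CTRL by edgeR at an adjusted p under 0.05, with 1 panel per concentration, the number of genes on the horizontal axis and the measured members in brackets. Lower calls among PPARα targets number 6, 12 and 10 in C1, C2 and C3, acute phase genes have 15 lower calls in C2 and 5 higher in C3, and sinusoidal endothelial markers have 10 higher calls in C2.

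Whether the concentrations changed transcripts in common was asked by counting shared calls. In all 3 treated groups 99 genes were called in the same direction, 40 higher and 59 lower. Without CTRL-2, CTRL-3 or CTRL-4 this overlap of calls between concentrations was 39, 39 and 41. It was 481 without C2-3, C2-4 and C3-4 and 1908 with the nuclear RNA index as a covariate, which averaged lower in CTRL than in each treated group. Atf3 stood at 12.3 ± 1.44 CPM in CTRL, 35.7 ± 2.98 in C1, 40.9 ± 10.5 in C2 and 47.0 ± 6.94 in C3. Chka rose by 0.92, 1.13 and 1.24 in log2 fold change in C1, C2 and C3, and the neutrophil-attracting chemokine gene Cxcl1 by 1.39, 0.84 and 1.24. The nuclear receptor gene Nr1h5 rose by 0.83, 1.12 and 0.89, and Slc17a8, a vesicular glutamate transporter gene, by 0.98, 0.93 and 0.82. Vnn1 fell to 7.17 ± 0.930, 9.78 ± 3.89 and 6.31 ± 1.80 CPM from 30.7 ± 4.48 in CTRL. Cd36 had log2 fold changes of -1.25, -1.33 and -1.32, and Pctp, a phosphatidylcholine transfer protein gene, of -1.0, -0.98 and -1.09. Retsat had -1.28, -1.17 and -0.97, and Sult2a3, a sulfotransferase with close relatives, -1.16, -1.27 and -1.36. Vnn1 lies on chromosome 10, 23894688 to 23905343.

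The 3 comparisons share the CTRL libraries. With unchanged groups simulated against those controls, edgeR gave 0 shared genes in each of 20 simulations, with at most 1 gene called per comparison. The simulation drew from the spread between libraries. A deviation of the control pool itself would enter all 3 comparisons alike, and neither the simulation nor a division of the control libraries removes it. Independent lists of these sizes would share 0.07 genes higher and 0.222 lower in all 3. C1 and C2 shared 305 calls in the same direction and 17 in opposite directions. Of the 305, 103 were higher and 202 lower, against 13.4 and 25.3 for independent lists. When each comparison was given 2 of the 4 control libraries, C1 and C2 shared 51 to 86 calls. C1 and C3 shared 105 (42 higher and 63 lower, against 0.872 and 2.16) and 11 in opposite directions, and 17 to 22 with divided controls. C2 and C3 shared 212 (72 and 140, against 7.47 and 15.98) and 4 in opposite directions, and 43 to 60 with divided controls.

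**Figure D3:**
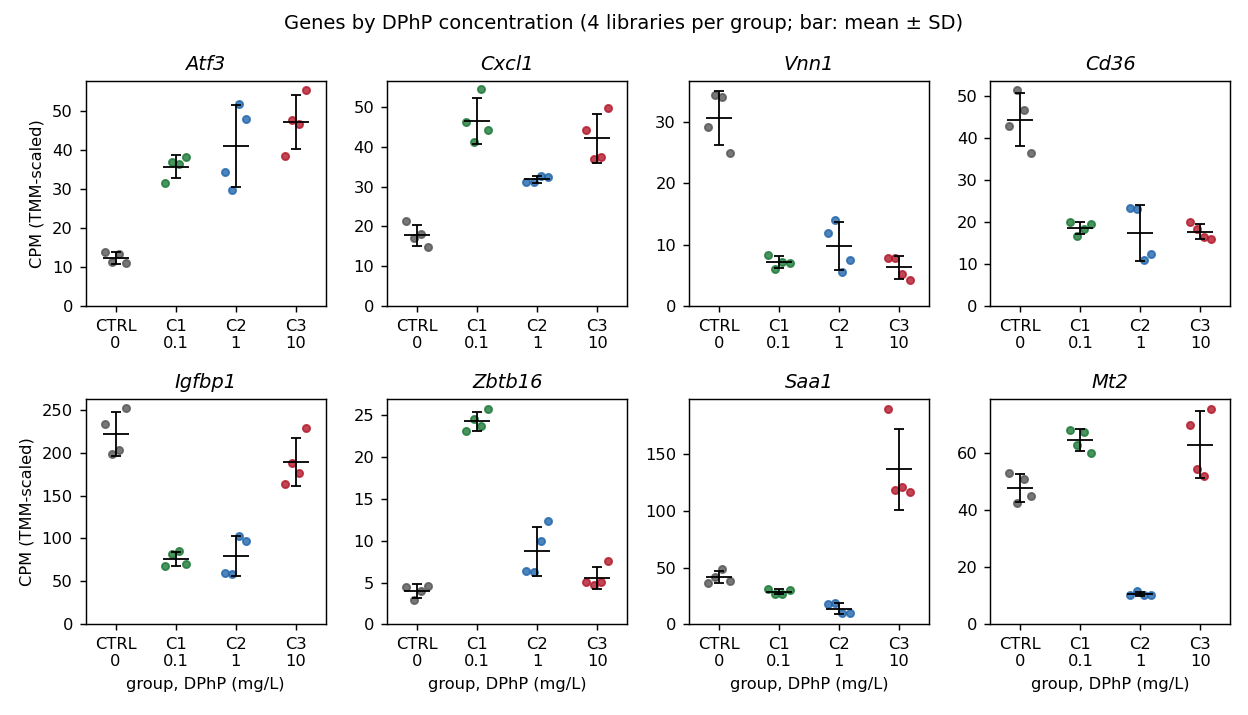
TMM-scaled CPM (vertical axis) of Atf3, Cxcl1, Vnn1, Cd36, Igfbp1, Zbtb16, Saa1 and Mt2 by group and DPhP concentration in mg/L (horizontal axis); points are libraries, 4 per group, and bars the mean ± SD. Atf3 is higher in C1, C2 and C3 (35.7, 40.9 and 47.0 CPM) than in CTRL (12.3), while Saa1 is lowest in C2 (13.8) and highest in C3 (137).

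The treated groups were then compared with each other, without the shared control. Between C3 and C1, 155 genes differed (63 higher and 92 lower in C3), of which 88 at least 2-fold. Saa1 was higher in C3 (log2 fold change 2.25 ± 0.21, edgeR adjusted p = 7.39e-06). Saa2 (1.91), Lcn2 (1.78), Adcy1 (1.86) and Apol10a (1.91), an apolipoprotein L family gene, were higher too. Zbtb16 was lower in C3 (log2 fold change -2.12 ± 0.21). Among intestinal genes, Sis had 379 counts in C1 and 3 in C3, Muc13 525 and 3, Reg1 596 and 5, Alpi 496 and 5, and Rbp2 310 and 6. Between C2 and C1, 366 genes differed (85 higher and 281 lower in C2), 128 of them at least 2-fold. Mt2 was lower in C2 (log2 fold change -2.61 ± 0.13), as were Zbtb16 (-1.5), Gsta1 (-1.97) and Cyp1a2, an aryl hydrocarbon receptor target (-1.11). Derl3 was higher (log2 fold change 2.42 ± 0.27). Between C3 and C2, 257 genes differed (209 higher and 48 lower in C3), 58 at least 2-fold. Saa1 (log2 fold change 3.28 ± 0.22), Saa2 (2.94), Lcn2 (2.81), Mt2 (2.57) and Mt1 (1.75) were higher in C3, and Derl3 (-1.14) and Ube2d2b (-1.54) lower. Derl3 lost that call without C2-4, C3-1, C3-2 or C3-3 (adjusted p up to 0.106). The C3 against C2 count was 14 with only the 8 libraries in the model, 2645 without C2-3, C2-4 and C3-4, and 117, 70, 72 and 442 without C2-1, C3-2, C3-3 or C3-4. The C2 against C1 count was 93 with only its 8 libraries in the model, 3459 without C2-3, C2-4 and C3-4, and 176, 196, 189 and 225 without C1-1, C1-2, C1-3 or C1-4. The C3 against C1 count was 81 without C1-1 and 630 without C2-3, C2-4 and C3-4.

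**Figure D4:**
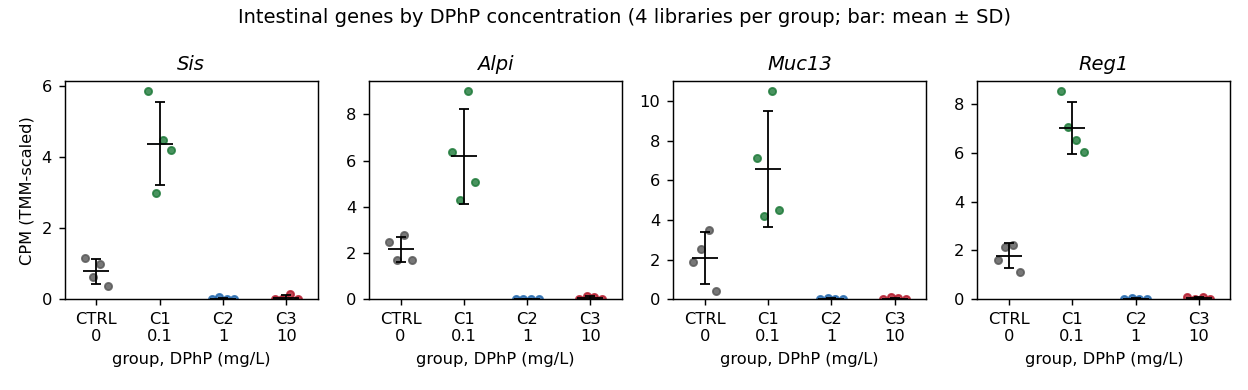
TMM-scaled CPM (vertical axis) of the intestinal genes Sis, Alpi, Muc13 and Reg1 by group and DPhP concentration in mg/L (horizontal axis), with 1 point per library and the mean ± SD of 4 libraries. Sis stands at 0.786 CPM in CTRL, 4.39 in C1, 0.0131 in C2 and 0.0372 in C3.

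Over the 3 comparisons with CTRL, camera called 61 of 135 list tests at its preset correlation. With an estimated correlation 1 held, the sinusoidal endothelial markers in C2. The median, the mean and the test of a list differed in sign in C1 for the bile acid, aryl hydrocarbon receptor, NRF2, stellate cell and adipocyte lists. They differed in C2 for mitochondrial DNA-encoded and ribosomal protein genes. In C3 they differed for the ATF4, male-biased, stellate cell, cholangiocyte, B and plasma cell and T and NK cell lists.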

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

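The tests of explanations in the last 3 paragraphs of this part were chosen after the results they address had been seen. In each group the highest or lowest library was compared with the other 3, and 39 values lay further from their nearest neighbour than Dixon's critical ratio for 4 libraries allows, of 470 groups of values examined; chance alone gives about 1 in 20, or 23.5. C3-4 held 14 of the 39 and C3-1 6.

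In C3-4, with the range of the other libraries of C3 in brackets, the share of counts in sense-intronic genes was 0.0219% (0.0107 to 0.0124) and the nuclear RNA index 9.97 (9.10 to 9.23). Nuclear-retained transcripts were high there, in CPM: Malat1 at 3632 (2106 to 2276), Neat1 at 1711 (975 to 1067) and Xist at 1804 (977 to 1084). Also high were Zbtb16 at 7.53 (4.72 to 5.05), Stab2 at 40.1 (25.7 to 28.0) and Clic3 at 8.86 (4.96 to 5.40). Low in CPM were Acadm at 176 (235 to 236), Creld2 at 20.97 (27.2 to 28.3), Aldh1b1 at 77.8 (129.6 to 139), Apoa4 at 272 (498 to 543), Hadha at 126 (236 to 257) and Cdh17 at 0 (0.0917 to 0.0991). C3-1 had a total of 33.2M counts (18.9M to 20.3M), and in CPM it was high in Saa1 at 189.7 (117 to 122), Saa2 at 72.2 (47.4 to 51.6), Cxcl9 at 16.5 (8.22 to 8.77) and Igkc at 5.93 (4.196 to 4.36) and low in Rbp2 at 0 (0.0856 to 0.0991). C3-3 was high in Sis at 0.149 (all at 0).

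Library C2-3 had a TMM scaling factor of 1.22 (0.915 to 0.944 in the other libraries of C2) and was high in Ube2d2b at 3.22 (2.41 to 2.48), in CPM. C2-2 was high in Mt2 at 11.6 (10.1 to 10.3), Sis at 0.0525 (all at 0), Reg1 at 0.0525 (all at 0) and Adh6a at 0.0262 (all at 0), C2-4 in Hist1h1d at 3.22 (1.46 to 1.69) and C2-1 in Prap1 at 0.141 (all at 0). Where the other libraries all stood at 0, any read gives the highest ratio, so such flags carry little. Sis, Reg1 and Adh6a in C2-2 lay below 0.0738 CPM, the value of 3 counts there. In C1, C1-2 was high in Derl3 at 1.74 (1.04 to 1.06) and Egfl7 at 27.7 (24.6 to 24.9) and low in Lcn2 at 8.21 (9.20 to 9.30). C1-4 was low in Acadm at 201 (218 to 220.5) and high in Ube2d2b at 2.18 (1.06 to 1.12) and C1-3 high in Ddit4 at 3.30 (2.14 to 2.32). Among controls, CTRL-1 was low in Acox2 at 89.4 (104 to 107) and Ephx1 at 106 (127 to 128), CTRL-2 low in Fam196a at 0.146 (0.935 to 0.970) and CTRL-4 high in Acads at 117 (75.2 to 77.0).

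The intestinal genes were highest in C1, lower in CTRL and close to 0 in C2 and C3. Pancreas carried along with some livers is argued against: the 13 pancreas markers other than Reg1 summed to 2.21 CPM in C1, below Reg1 alone at 6.87 in pooled CPM. Intestinal tissue carried along with some livers stays open: of 20 intestinal markers not looked at before, 10 had at least 20 counts and 7 of these had the order C1, CTRL, then C2 and C3 (0.833 expected by chance), short of the 75% set for that test. Liver expresses some of these markers, and 4 had at least 20 counts in both C2 and C3. A response to DPhP also stays open, with a median log2 fold change of 1.59 in C1, because each concentration is 1 pool.

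More nuclear or unspliced RNA in C2-3, C2-4 and C3-4 is a candidate explanation for their position: the lowest share of counts in sense-intronic genes among them was 0.0219%, above the highest of the other 13 libraries at 0.0138%. A lower share of hepatocytes stays open, as markers of other cells go both ways in log2 ratio to the other libraries of the group. Hepatocyte markers had ratios from -1.17 to -0.646, macrophage from -0.741 to -0.433 and erythroid from -1.22 to -0.433. Sinusoidal endothelial had 0.220 to 0.245, neutrophil 0.463 to 0.572, T and NK cell 0.161 to 0.350 and B and plasma cell 0.0586 to 0.294. Whether these libraries made the C2 count the largest cannot be told. Without them it was 5177, but the C1 count, with none of them, rose to 2688 too (C3 1125). No biological explanation was tested, since the libraries of a group come from 1 pool.

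Of the 18 measured glucocorticoid responsive genes 8 fell in C1 and 14 in C2. More recent feeding in these pools stays open, as medians of log2 fold change in C1 go both ways. Fatty acid and triglyceride synthesis genes, which feeding raises, had -0.24. PPARα targets and ketone body genes, which it lowers, had -0.21 and -0.57, and cholesterol synthesis genes, which it raises, 0.17. Another time of day stays open: clock genes peak at different times, so the camera adjusted p of 0.228 in C2 excludes nothing, and for change in either direction fry gave adjusted p = 0.000117 in C1, 0.000232 in C2 and 0.000221 in C3, but it called 24, 36 and 21 of all 45 lists there, which does not single out the clock. A response to DPhP stays open too, with a median log2 fold change of the glucocorticoid responsive genes of -0.20 in C3, since pool and concentration cannot be told apart. Time of harvest and feeding are not given in the sources used here.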

How the results depend on the processing

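The alternatives without C2-3, C2-4 and C3-4, with the nuclear RNA index as a covariate and with protein-coding genes alone were chosen after seeing the data; the others were planned. With 1 library left out in turn, the counts of changed genes were 159 to 294 for C1 against CTRL (414 with all libraries), 1972 to 4492 for C2 (3254), 97 to 210 for C3 (249), 176 to 430 for C2 against C1 (366), 81 to 146 for C3 against C1 (155) and 70 to 442 for C3 against C2 (257). The 2-fold counts were 64 to 99 in C1 (106), 624 to 1320 in C2 (903) and 46 to 75 in C3 (82). The overlap of calls between concentrations, all 3 groups, was counted only with a CTRL library left out and was 39 to 66 (99). Size factors, upper-quartile scaling, limma-voom and the replicate block moved none of these counts by over 1.5 times. With upper-quartile scaling the median log2 fold change of all genes was 0.10 in C2, against 0.029 with TMM. DESeq2 called 924 genes in C1 (193 at 2-fold), 768 in C3 (161), 762 for C2 against C1, 289 for C3 against C1, 600 for C3 against C2 and 306 in the overlap. With only the 2 groups compared in the model the counts were 2557 in C1 (322 at 2-fold), 1492 in C2 (505), 93 for C2 against C1, 14 for C3 against C2 and 154 in the overlap. Against a null of a 1.2-fold change, glmTreat called 122, 1317 and 67 genes in C1, C2 and C3 and 19 in the overlap, as its wider null leaves fewer. The stricter filter, which tests fewer genes, gave 50, 211 and 29 genes at 2-fold in C1, C2 and C3 and 91 for C3 against C1, no filter 167 for C3 against C2, and protein-coding genes alone 307 at 2-fold in C2 and 144 for C3 against C2. Without C2-3, C2-4 and C3-4 the counts were 2688 in C1 (374 at 2-fold), 5177 in C2, 1125 in C3 (147), 3459 for C2 against C1, 630 for C3 against C1, 2645 for C3 against C2 and 481 in the overlap; 414, 2336 and 249 of the C1, C2 and C3 calls were among them. With the nuclear RNA index as a covariate they were 3807 in C1 (269 at 2-fold), 5542 in C2, 3027 in C3 (209), 2054, 703 and 1751 between treated groups and 1908 in the overlap; 411, 1758 and 237 of the C1, C2 and C3 calls were among them, and 76 of the 3254 C2 calls changed sign. Where neither the smaller number of genes nor the wider null is named, the cause was not tested.

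Among named genes, 425 values were followed. Without C2-3, C2-4 and C3-4, mt-Co1 in C2 turned to a log2 fold change of 0.43. With the nuclear RNA index as a covariate 27 values turned; of these Gdf15 in C2 had been called (0.95) and none of the 27 was past the threshold in both fits. In log2 fold change they were, in C1, Alb 0.46, Cd5l 0.39, Dnaja1 0.30, Hpx 0.65, Perp 0.27, Rpl4 0.22, Serpina1c 0.31 and Serpina1e 0.24. In C2 they were Car3 0.36, Gdf15 -0.12, Lipe -0.62, mt-Co1 0.53 and Pcna 0.31, and in C3 Apoa2 0.28, B2m 0.31, Bhlhe40 -0.31, Car3 0.36, Cd5l 0.48, Cps1 0.30, Dnaja1 0.40, Hspa5 0.37, Hspa8 0.34, mt-Co1 0.44, Mup1 0.36, Pemt 0.54, Rgs5 0.47 and Rpsa 0.69. The cause was not tested. In the other alternatives no named gene turned, and calls were lost by 7 values with size factors, 23 with upper-quartile scaling, 54 without the filter, 11 with the stricter filter, 0 with DESeq2, 9 with limma-voom, 47 with only the 2 groups compared and 115 with glmTreat. Of gene list tests, 61 of 135 were called by camera at its preset correlation, 1 with an estimated correlation and 45 by fry. Oxidative phosphorylation turned upward in C2 without C2-3, C2-4 and C3-4 (camera adjusted p = 0.0124) and with the covariate (adjusted p = 4.57e-06, and 5.74e-07 in C3). With the covariate, proteasome subunits turned in C1, C2 and C3 (adjusted p = 0.000600, 0.000320 and 2.40e-05), and female-biased genes in C1 and C2 (adjusted p = 0.0459 and 0.0190).

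Libraries with the same replicate number did not deviate together: over 24 pairs the median correlation was 0.0306 (-0.299 to 0.51). Of these, 8 were over 0.1, and in 6 the best match was the same number. With the replicate number as a block the counts were 435, 3426 and 256 in C1, C2 and C3, 14 values of named genes lost their call and 1 gained it. Of simulated 1.5-fold changes edgeR recovered 19.4% to 31.3%, so changes under 2-fold may often be missed.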

Other observations

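The divisions of the libraries in this part were counted after the results had been seen. Among B and plasma cell markers, 2 of 10 rose and 0 fell in C1, 4 rose and 1 fell in C2, and 0 rose and 1 fell in C3 (edgeR; 2 and 0, 4 and 1, and 0 and 2 adjusted over the list alone). Of genes chosen after their values were seen, Ighd, the heavy chain of IgD, rose in C2 (log2 fold change 1.02, edgeR adjusted p = 0.00774). Igha, the heavy chain of IgA, rose from 7.87 ± 2.2 CPM in CTRL to 17.7 ± 3.77 in C1 (log2 fold change 1.17 ± 0.26, edgeR adjusted p = 0.0203) and fell to 1.498 ± 0.754 in C2 (-2.31 ± 0.29) and 1.59 ± 0.142 in C3 (-2.31 ± 0.29). Jchain, the joining chain of IgA and IgM, rose in C1 (3.48 ± 1.12 to 7.91 ± 2.41 CPM) and fell in C2 (1.92 ± 0.354). In C3 it had 1.89 ± 0.221 (edgeR adjusted p = 0.0945). Igha and Jchain had the order of the intestinal genes. Igkc, the κ light chain, rose in C1 (log2 fold change 1.06) and fell in C3 (-0.83, edgeR adjusted p = 0.0486). In C2 it had -0.20 (adjusted p = 0.502). Calls were lost without C1-1, C1-3, CTRL-1, CTRL-2 or CTRL-4 for Igha in C1 (edgeR adjusted p up to 0.0844), without C1-1 or C1-4 for Jchain in C1 (up to 0.0634), and without C2-1, C2-3, C2-4, CTRL-1, CTRL-2 or CTRL-3 for Jchain in C2 (up to 0.108, and 0.0703 without C2-3, C2-4 and C3-4). The fall of Igkc in C3 lost its call without C3-2, C3-3, C3-4, CTRL-1, CTRL-2 or CTRL-3 (up to 0.18), and with limma-voom.

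Each count of changed genes was set against the other ways to divide the same 8 libraries into 4 and 4, of which there are 35. For C1 against CTRL 1 of 35, the real one, gave as many as 414 genes and 1 as many as 106 at 2-fold, with 0 and 0 as the highest of the others, so a chance division of the libraries can be excluded at that level. With 1 pool per group, these divisions address technical spread only, and say nothing of differences between pools that would arise without DPhP. For C2 it was 1 for 3254 genes and 1 for 903 (highest others 2746 and 333), the highest with C2-1, C2-2, CTRL-2 and CTRL-3 on 1 side. For C3 it was 1 for 249 and 1 for 82 (highest others 0 and 0), for C2 against C1 1 for 366 (0) and for C3 against C1 1 for 155 (0). For C3 against C2, 5 of 35 divisions gave as many as 257 genes, and a chance division of the libraries cannot be excluded. The highest was 6809, with C2-1, C2-2, C3-1 and C3-3 on 1 side, several times the real count, which points to a structure of the samples: each of the 4 other divisions put C2-3, C2-4 and C3-4 on the same side.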
